A study of Mus musculus with 3 samples.

How the data were processed

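RNA was sequenced from conventional dendritic cells sorted from the lungs of untreated C57BL/6 mice at postnatal day 7. Per the labels' protocols, lungs of 2 to 3 litters were digested with collagenase and DNase, enriched on magnetic beads against CD11c, stained and sorted. The sort kept lineage-negative cells positive for MHC class II and CD11c and parted them into CD11b, CD103hi and CD103int cells. The labels give 1 sample per subset, and the design text gives 2 replicates of each. The deposited tables hold 2 value columns per subset, named by subset and by 1 or 2, and these 6 columns were taken as the replicates. No label says that the replicates came from separate animals or litters, so p-values of single genes measure only the spread between these libraries, which may be technical.

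Per the file headers, the authors deposited a table of log2 normalized CPM (counts per library scaled to a common size), a table of log2 RPKM and 3 tables of their own pairwise comparisons. Both value tables list 11435 genes. Log2 RPKM differs from log2 CPM by a constant for each gene (largest spread over columns 1.0e-06). Per the file headers, the comparison tables hold the authors' log2 fold change, mean log2 CPM, an F score, a p-value and an adjusted p-value for each gene. The submitters' processing notes name TopHat2 2.0.14 and 2.1.0, Cufflinks 2.2.1.0, Cuffdiff 2.2.1, Cuffnorm 2.2.1 and the mm10 genome build, with no role for each. The program behind the deposited log2 values and F scores, the gene annotation and the handling of strand are not given in the sources used here. A filter on low genes before deposit cannot be ruled out, and genes outside the tables were not analysed here.

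The steps between low CPM values gave back whole reads. In every library 100% of the values under 1000 reads lay within 0.1 of a whole number. Listed genes held 19831853 to 25852575 reads per library, and the scaling factors by which the normalization changed library sizes ran from 0.845 in CD103int replicate 1 to 1.07 in CD11b replicate 1. The 10 genes with the most reads took 9.09% to 14.9% of the reads of a library. The lowest log2 CPM, reached at 0 reads, was -4.50, and 3 reads, the bound that a count of 0 allows for counting error alone, correspond to a log2 CPM of -2.63 to -2.36.

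The unit is log2, so the main test was limma (3.58.1, R 4.3.3) on the deposited log2 CPM, with a mean-variance trend, 1 fit over all 6 libraries and 3 pairwise contrasts. P-values were two-sided and adjusted by Benjamini and Hochberg over the 11435 genes, with a threshold of 0.05. A filter of log2 CPM above 0 in at least 2 columns removed 0 genes. Errors of fold changes are limma's standard errors (SE), and errors of levels are standard deviations (SD, n = 2). This fit has no replicate term and is called the unpaired fit. It was set, with the lists, the rule for named genes and most alternatives, before the data were examined.

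The paired fit adds the replicate number as a block. What the number marks is not given in the sources used here. Deviations of replicates from their subset means correlated across genes for every pair of subsets (0.257 for CD11b and CD103hi, 0.319 for CD11b and CD103int, 0.621 for CD103hi and CD103int). The authors' deposited fold changes were set beside negative binomial models with and without the replicate number as a term, at 6 dispersions from 0 to 0.5, over genes with at least 20 reads in every library. With the term, the standard deviation of the difference was 0.0024, 0.0025 and 0.0028 for the 3 comparisons at a dispersion of 0.1, and at most 0.0235 at any dispersion above 0. At a dispersion of 0 it was 0.136, 0.110 and 0.160, near the values without the term, which were 0.103 or more at every dispersion. On these grounds the numbers were read as pairing the libraries. That reading was made after the calls of both fits had been seen, so both fits are reported, with the paired value beside the count or camera call of a described list that it changes. Fold changes are the same in both fits.

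There were 30 gene lists, covering cDC lineages, maturation, immune functions, metabolism, cell cycle, tissue dissociation stress and the other cell types that a lung cell sort could hold. Members were matched by symbol, with A530099J19Rik, Ppap2a and 4632428N05Rik taken as Gpr141b, Plpp1 and Vsir. Lists with at least 5 listed members were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of 1 comparison. Camera with an estimated correlation and fry were the alternatives. Camera tests a list against the other genes, while fry tests whether the genes of a list change on balance and compares them with no other genes. At the preset correlation camera takes genes as nearly independent, so its p-values rest mainly on the spread over genes. Genes are not independent replicates, and very small camera values do not measure the spread between libraries. Ranges of adjusted p over alternatives are those of camera, without fry. No list in any comparison kept an adjusted p under 0.05 with an estimated correlation. That test has only the residual degrees of freedom of the fit, 3 in the unpaired fit and 2 with the block. With the preset correlation they come from the number of genes instead. A high value with an estimated correlation may thus reflect the few libraries as well as correlated genes, and cannot tell these apart. The lowest such values were adjusted p = 0.126 for CD11b versus CD103hi, 0.251 for CD103int versus CD103hi and 0.314 for CD103int versus CD11b.

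Named genes followed a rule. They are the genes of the sort markers, up to 6 largest rises and 6 largest falls per comparison, and up to 2 rises and 2 falls per list. For the genes higher in 1 subset than in both others, they are the 6 with the largest smaller fold change at the same level. Rises and falls had to pass the threshold, and the 6 largest also needed replicates that did not overlap and a mean log2 CPM of at least 4 in the higher subset. Predicted genes, receptor segments and pseudogenes were left out. In a list with no passing gene, the rule takes the 2 members of smallest p as values. Not every gene under the rule is printed, and for some lists, such as the cell cycle list, none is. The rule was applied to the paired fit as well, after the data had been seen. Coordinates are from GENCODE M21 on mm10, which holds 11023 of the listed symbols. Whether reads were split between close relatives, such as the Cd209, Ear, Clec4 and H2 families, or between a gene and an antisense partner, is not given in the sources used here, and values of such genes are uncertain.

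The overlap of 2 comparisons that share a subset was set beside the overlap of independent lists and beside 100 simulations of unchanged groups. The fits were tested on simulated data over the 11435 genes, with 100 genes changed 4-fold and 100 changed 16-fold. For CD11b versus CD103hi, the unpaired fit recovered 48 and 82 of these and the paired fit 71 and 99. For CD103int versus CD103hi, the counts were 36 and 83, and 74 and 95. For CD103int versus CD11b, they were 40 and 91, and 75 and 95. False calls numbered 7 of 137, 3 of 122 and 3 of 134 calls in the unpaired fit and 11 of 181, 23 of 192 and 13 of 183 in the paired fit. The paired shares are above the threshold of 0.05 in all 3 comparisons, most so for CD103int versus CD103hi, where every gene call rests on that fit. The unpaired share for CD11b versus CD103hi was also just above it. The threshold bounds such a share only on average, and each share comes from a single simulated data set. A small excess therefore shows little.

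Alternatives changed the unit, the filter, the added constant, the normalization, the variance trend, the libraries in the fit, the block, a fold threshold and the list test, and left out each library in turn. Alternatives chosen after seeing the data were limma-voom on the recovered reads with and without the block, the mean of the alveolar macrophage list as a covariate, leaving out replicate 2 of both CD103hi and CD103int, the block with CD103int replicate 2 left out, the block together with an estimated correlation in camera, and the lists without the genes of the sort markers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, bootstrap intervals and plots.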

Results

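Gene expression was profiled by RNA sequencing in 3 subsets of conventional dendritic cells (cDCs), the antigen-presenting cells that prime T cells, from the lungs of C57BL/6 mice at postnatal day 7. CD11b cells were sorted on the integrin CD11b and the receptor SIRPa, CD103hi cells on a high level of the integrin CD103 and the chemokine receptor XCR1, and CD103int cells on an intermediate level of CD103, with XCR1 per the series' design and the migration receptor CCR7 per the sample labels. Each subset had 2 libraries, replicates 1 and 2, so 6 libraries were compared over 11435 genes. Reads in these genes numbered 23197365 and 19831853 in CD11b, 25852575 and 20488002 in CD103hi, and 23586948 and 22328659 in CD103int. Levels are log2 CPM as normalised by the authors. Differences are log2 fold changes from limma with their SE, tested in an unpaired fit and in a paired fit that adds the replicate number as a block. List tests with camera are those of the unpaired fit unless the paired fit is named.

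The genes of the sort markers were checked first. Itgae, which encodes CD103 (mm10 chromosome 11, 73090583 to 73147446, plus strand), stood at 10.54 ± 0.20 (SD, n = 2) in CD103hi, 6.96 ± 1.22 in CD103int and 3.38 ± 0.33 in CD11b. Xcr1 (chromosome 9, 123852315 to 123862029, minus strand) followed the same order, at 10.05 ± 0.27, 7.66 ± 0.18 and 2.01 ± 0.36. Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491, plus strand), was 9.55 and 9.27 in the CD11b libraries, -0.85 and 3.35 in CD103hi, and 3.11 and 5.66 in CD103int. Ccr7 (chromosome 11, 99144196 to 99155077, minus strand) was 13.05 and 10.63 in CD103int, 9.32 and 6.81 in CD103hi, and 8.13 and 7.84 in CD11b. Sirpa (chromosome 2, 129592835 to 129632228, plus strand) was 10.46 and 9.80 in CD11b, 3.52 and 7.82 in CD103hi, and 7.79 and 10.62 in CD103int. Itgax, which encodes CD11c, was 8.22 to 9.29 in 5 libraries and 7.40 in CD103int replicate 1. The MHC class II gene H2-Ab1 stood between 12.17 and 14.56 in all 6. These genes encode markers used in the sort, so by themselves they only check the labels. Several are also members of lists tested here, Xcr1 and Itgae of the cDC1 list, Itgam and Sirpa of the cDC2 list, Ccr7 of the mature migratory list, Ccr7 and Xcr1 of the receptor list and H2-Aa, H2-Ab1 and H2-Eb1 of the MHC class II list, and enter the counts, medians and tests of those lists. Without them, the cDC1, cDC2 and mature lists kept their camera calls and directions in each comparison where they had been called, with medians of -3.90 and 4.83 for cDC1 and cDC2 genes in CD11b versus CD103hi, -1.50, 2.76 and 3.17 for cDC1, cDC2 and mature genes in CD103int versus CD103hi, and 1.71, -2.32 and 3.03 in CD103int versus CD11b. Leaving out these genes does not undo the sort, which picks whole cells by their markers. Other list genes expressed in the same cells can be selected with them, so the kept calls do not test the lists apart from the gate.

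**Figure D1:**
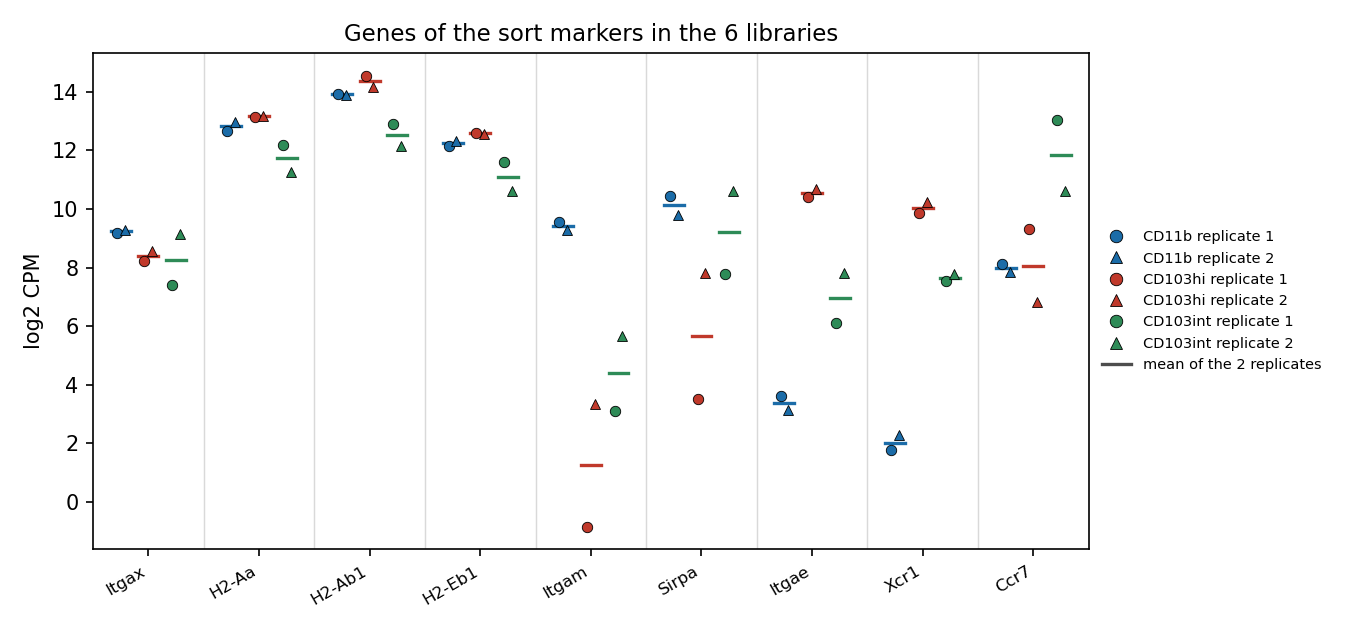
Log2 CPM of the genes of the sort markers in each library. Circles are replicate 1, triangles replicate 2 and bars the mean of both; Itgae and Xcr1 order the subsets as CD103hi, CD103int and CD11b, while Sirpa differs by over 2 log2 units between the replicates of CD103hi (3.52 and 7.82) and of CD103int (7.79 and 10.62).

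Replicates were alike to different degrees. Across genes, log2 CPM of the replicates correlated at 0.959 in CD11b, 0.924 in CD103hi and 0.843 in CD103int. The share of genes over 2-fold apart was 10.7%, 12.1% and 35.0%. CD103int replicate 2 correlated at 0.892 with CD11b replicate 2 and at 0.884 with CD103hi replicate 2. Genes are not independent replicates, so these correlations only describe the libraries. The median of 23 alveolar macrophage genes was 5.38 and 6.29 in CD11b, 1.31 and 5.28 in CD103hi, and 4.62 and 8.12 in CD103int. The median of 42 cell cycle genes was also higher in replicate 2, at 4.24 and 5.77 in CD11b, 5.37 and 6.06 in CD103hi, and 3.10 and 5.96 in CD103int. Neutrophil genes, with a median over 9 genes of 1.04 and 2.55, -2.31 and 1.81, and 0.48 and 4.82, and lung epithelial genes, with a median over 12 genes of 0.17 and 3.73, 1.86 and 3.22, and 2.37 and 4.41, went the same way. The median of 39 mature migratory DC genes went the other way, at 5.91 and 5.44, 6.67 and 4.52, and 9.90 and 7.45.

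**Figure D2:**
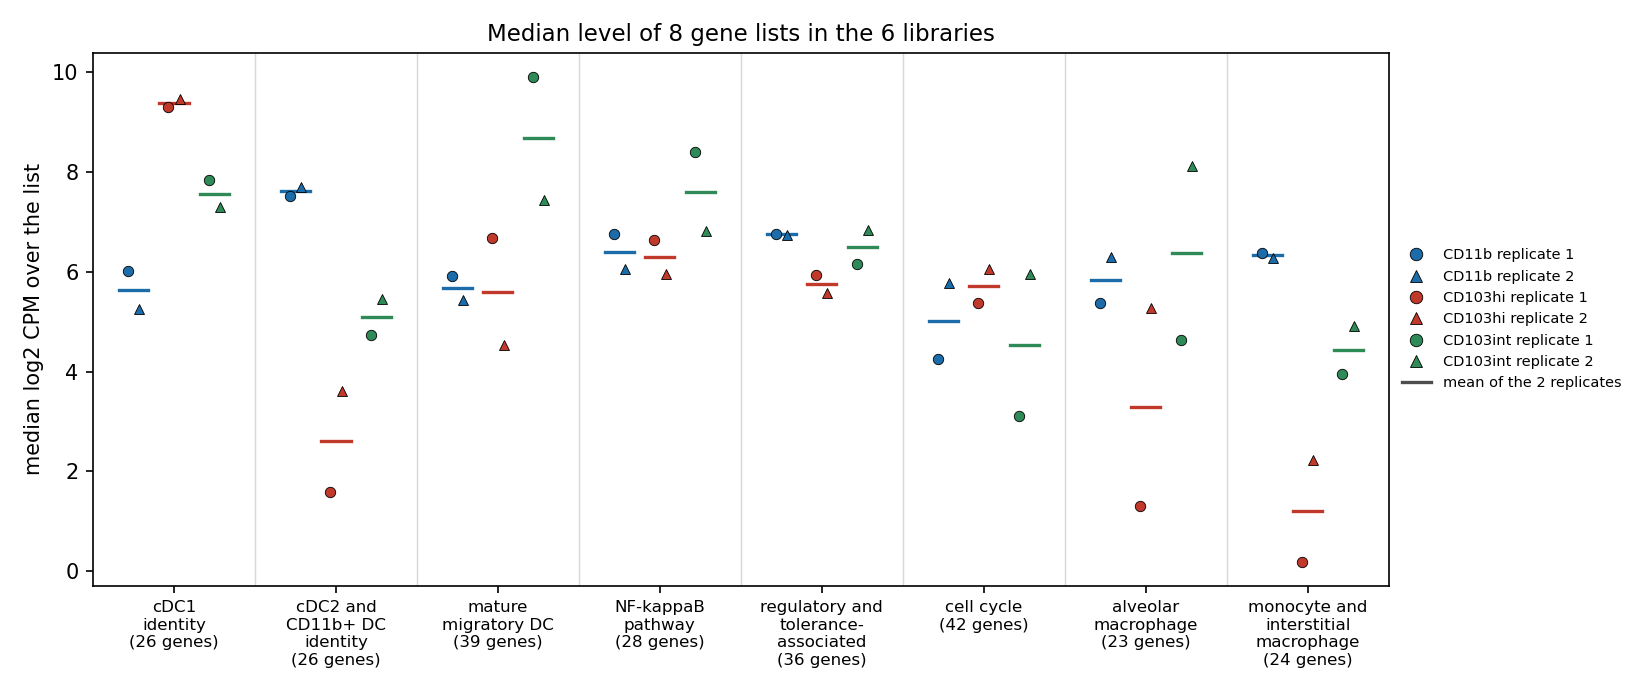
Median log2 CPM over the genes of 8 lists in each library, with circles for replicate 1, triangles for replicate 2 and bars for the mean of both. The cDC1 list lies highest in CD103hi (9.30 and 9.46), the cDC2 list in CD11b (7.52 and 7.71) and the mature list in CD103int (9.90 and 7.45), and the alveolar macrophage list is higher in replicate 2 of every subset.

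CD11b and CD103hi cells were compared to describe the subsets at either end of the CD103 range. Genes of the cDC1 lineage, the cDCs that cross-present antigen to CD8 T cells, were higher in CD103hi, and genes of the cDC2 lineage were higher in CD11b. Gcsam, a signalling adaptor gene first described in germinal centres (chromosome 16, 45610380 to 45622867, plus strand), was 265-fold lower in CD11b (log2 fold change -8.05 ± 0.29 SE, n = 2 per subset, adjusted p = 0.000964). Cd209a, a C-type lectin of the DC-SIGN family (chromosome 8, 3743397 to 3748984, minus strand), was higher in CD11b by 9.85 ± 0.51 on the log2 scale (adjusted p = 0.00222), from 0.65 ± 1.03 (SD) to 10.49 ± 0.26. Monocyte and macrophage genes were higher in CD11b too, with the scavenger receptor gene Cd163 up by 8.76 ± 0.66 (adjusted p = 0.00445) and the complement gene C1qb by 6.94 ± 0.73 (adjusted p = 0.0112).

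Of 26 cDC1 genes, 17 were lower in CD11b and none higher (22 lower when adjusted over the list alone; 19 in the paired fit), with a median of -4.26, a 19.2-fold difference. Camera gave an adjusted p of 3.08e-32, and adjusted p = 0.126 with an estimated correlation. Of 26 cDC2 genes, 10 were higher in CD11b and none lower (24 adjusted over the list alone), with 20 in the paired fit and a median of 4.83. For these genes camera gave adjusted p = 3.25e-23, and adjusted p = 0.126 with an estimated correlation. Of 24 monocyte and interstitial macrophage genes, 8 were higher in CD11b (17 adjusted over the list alone, 16 in the paired fit), with a median of 4.04 (camera adjusted p = 5.07e-17, and adjusted p = 0.330 with an estimated correlation). The alveolar macrophage list had a median of 2.01 and no gene past the threshold in the unpaired fit, 1 adjusted over the list alone and 4 in the paired fit (camera adjusted p = 5.56e-04, and adjusted p = 0.730 with an estimated correlation). Without CD103hi replicate 1 that median was 0.10 and the camera call was lost (adjusted p = 0.622; 5.32e-22 to 0.893 over all alternatives). The 39 mature migratory DC genes had a median of 0.32 with a camera direction of down (adjusted p = 0.712), with 1 gene lower (also adjusted over the list alone) and 4 lower in the paired fit. Without CD103hi replicate 1 their median was 1.18 (adjusted p = 0.00196), and without CD103hi replicate 2 it was -1.04 (adjusted p = 1.92e-04; 1.41e-08 to 0.967 over all alternatives). Neutrophil genes had a median of 2.63, with all 9 fold changes positive. None was past the threshold in the unpaired fit, also when adjusted over the list alone, and 2 were in the paired fit. Their camera call (adjusted p = 0.0320, and adjusted p = 0.730 with an estimated correlation) was lost without CD11b replicate 2 (0.120) or CD103hi replicate 1 (0.513) and with quantile normalization (0.0610), with 1.10e-07 to 0.786 over all alternatives. The cell cycle list had a median of -0.58 and no gene past the threshold in either fit. Camera did not call it in the unpaired fit (adjusted p = 0.0617) but did in the paired fit (0.00151, and adjusted p = 0.703 with the block and an estimated correlation). It was also called without CD11b replicate 2 (7.42e-05), CD103hi replicate 1 (0.00127), CD103int replicate 1 (0.00761) or CD103int replicate 2 (0.00798), with 1.09e-12 to 0.836 over all alternatives.

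Genes of immune functions differed in both directions. Of 19 chemokine genes, 4 were higher in CD11b and none lower (5 higher and 1 lower adjusted over the list alone; 7 and 1 in the paired fit), among them the eosinophil attractant Ccl24 (7.37 ± 1.14, adjusted p = 0.0306) and Ccl9 (5.64 ± 0.86). In camera, adjusted p was 2.37e-05 for the list, and adjusted p = 0.211 with an estimated correlation. Of 26 chemoattractant receptor genes, C3ar1 (5.52 ± 0.52) and Ltb4r1 (3.28 ± 0.36) were higher in CD11b, and 3 were lower, including Cxcr3 (-6.27 ± 0.45). Adjusted over the list alone, 11 were higher and 4 lower, and in the paired fit 9 and 4; the camera call (adjusted p = 0.0438, and adjusted p = 0.342 with an estimated correlation) was lost without CD11b replicate 1 (0.0814) or 2 (0.165), with 0.00507 to 0.351 over all alternatives. Of 36 interferon response genes, 6 were higher, including Rtp4 (6.04 ± 0.76) and Oas2 (5.07 ± 0.87). Adjusted over the list alone, 15 were higher and 2 lower, and in the paired fit 14 and 1 (camera adjusted p = 2.37e-05, and adjusted p = 0.559 with an estimated correlation). Of 36 regulatory and tolerance-associated genes, 3 were higher and 2 lower (6 and 3 adjusted over the list alone; 6 and 3 in the paired fit), with a median of 0.83. The higher ones included the inhibitory receptor gene Lilrb4a (3.41 ± 0.40) and Socs3 (3.39 ± 0.48), a brake on cytokine signalling, and the lower ones were the inhibitory receptor genes Btla (-4.25 ± 0.50) and Havcr2 (-1.67 ± 0.29). The list test gave adjusted p = 0.00571, adjusted p = 0.263 with an estimated correlation, and adjusted p = 0.0918 without CD11b replicate 1 (8.40e-05 to 0.281 over all alternatives). The sensors of microbial nucleic acid and protein Tlr3 (-5.60 ± 0.32) and Tlr12 (-6.02 ± 0.62) were lower in CD11b. The 31 microbial pattern recognition genes had 3 lower and none higher in the unpaired fit. In the paired fit 8 were higher and 3 lower, and the list median was 0.81. Of 24 cholesterol genes, only Mvd (1.56 ± 0.27) was higher (6 adjusted over the list alone; 2 in the paired fit), with a camera adjusted p of 1.60e-04, and adjusted p = 0.175 with an estimated correlation. Of 16 cytokine genes, 2 were higher (4 higher and 1 lower adjusted over the list alone, and as many in the paired fit), with a median of 1.13. Camera did not call that list in the unpaired fit (adjusted p = 0.0642) but did in the paired fit (0.0386, and adjusted p = 0.404 with the block and an estimated correlation). It was also called without CD103hi replicate 2 (0.0301; up to 0.404 over all alternatives). Of 24 MHC class I and cross-presentation genes, none passed in the unpaired fit, also when adjusted over the list alone, and 3 were lower in CD11b in the paired fit, with a median of -0.55. The camera call of lower levels (adjusted p = 0.0438, and adjusted p = 0.730 with an estimated correlation) was lost without CD11b replicate 1 (0.129) or 2 (0.0668), without CD103hi replicate 1 (0.108) and with quantile normalization (0.0648), with 0.00117 to 0.730 over all alternatives.

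The largest rises in CD11b included Retnla, a resistin-like secreted protein (10.02 ± 1.52, adjusted p = 0.0297), and Fcrls (9.36 ± 1.28), and the largest falls included Cd207, which encodes langerin (-9.03 ± 1.22), the peptidase gene Naalad2 (-8.92 ± 0.97) and Cyp8b1 (-7.40 ± 0.49). The unpaired fit called 339 of the 11435 genes, 167 higher and 172 lower in CD11b, the paired fit 861 (495 and 366) and the authors' deposited comparison 716 (401 and 315), and both larger sets held all 339. Without CD11b replicate 1 or 2 the count was 22 or 2, without CD103hi replicate 1 or 2 it was 80 or 173, and without CD103int replicate 1 or 2 it was 907 or 913.

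CD103int and CD103hi cells, which both carry XCR1 per the series' design, were compared to describe what marks the intermediate cells. Genes of mature migratory DCs, the state in which DCs travel to lymph nodes, were higher in CD103int, and genes of the cDC1 lineage were lower. Ccl5, a chemokine that attracts T cells (chromosome 11, 83525778 to 83530518, minus strand), was higher in CD103int by 5.32 ± 0.95 in the paired fit (adjusted p = 0.0328), with levels of 12.72 and 8.98 against 7.89 and 3.18. The transcription factor gene Irf1 was higher by 4.00 ± 0.41 (paired adjusted p = 0.0204), and Sept3, a cDC1-associated septin, was lower (-3.27 ± 0.26, paired adjusted p = 0.0204). These calls rest on the paired fit, since limma called 0 genes in the unpaired fit, where the lowest adjusted p was 0.0805 and 1836 genes had an unadjusted p under 0.05. In a single simulated data set, 23 of 192 calls of the paired fit in this comparison were false, a larger share than the 0.05 that the threshold allows on average.

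Of 39 mature migratory DC genes, of which Ccr7 encodes a marker that the sample labels give for the sort of CD103int, 30 were higher in CD103int in the paired fit and none lower, and 33 in the unpaired fit when adjusted over the list alone. Their median was 3.18, a 9.06-fold difference, and 38 of the 39 fold changes were positive. Examples were Ankrd33b (4.77 ± 0.65, paired adjusted p = 0.0216), Socs2 (4.08 ± 0.63) and Samsn1 (3.47 ± 0.48). Camera gave an adjusted p of 8.45e-16, and adjusted p = 0.496 with an estimated correlation. Of 28 NF-kappaB pathway genes, 8 were higher in the paired fit, including Relb (3.04 ± 0.39) and Tank (2.84 ± 0.51), and 1 in the unpaired fit when adjusted over the list alone. For these genes camera gave adjusted p = 1.00e-07, and adjusted p = 0.576 with an estimated correlation. Of 18 co-stimulatory and adhesion ligand genes, 4 were higher in the paired fit and none passed in the unpaired fit or when adjusted over the list alone there. Vcam1 (3.39 ± 0.58) and Slamf1 (3.19 ± 0.59) were among them, while Cd86, a ligand for T cell activation, was -1.30 ± 0.35 and did not pass. In camera, adjusted p was 0.00695 for these ligands, adjusted p = 0.604 with an estimated correlation, and adjusted p = 0.132 without CD103int replicate 1 (1.17e-06 to 0.604 over all alternatives).

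Of 26 cDC1 genes, 13 were lower in CD103int in the paired fit and 18 in the unpaired fit when adjusted over the list alone, with a median of -1.55 (camera adjusted p = 5.27e-15, and adjusted p = 0.270 with an estimated correlation). The cross-presentation receptor gene Clec9a fell by 1.61 ± 0.31 and Tlr3 by 2.18 ± 0.33 in that fit. Of 26 cDC2 genes, 9 were higher and 1 lower in the paired fit (10 and 1 in the unpaired fit when adjusted over the list alone), with a median of 2.99. Over all alternatives that median ran from 1.04 to 3.68. Cd209a was higher (4.05 ± 0.46) and Mgl2, another C-type lectin, lower (-2.29 ± 0.45); camera gave an adjusted p of 2.90e-07, and adjusted p = 0.270 with an estimated correlation. Of 36 regulatory and tolerance-associated genes, 8 were higher and 2 lower in the paired fit (6 and 2 in the unpaired fit when adjusted over the list alone). Arg2, an arginine-degrading enzyme (3.86 ± 0.72), Cd274, which encodes the inhibitory ligand PD-L1 (2.60 ± 0.31), and Lilrb4a (2.35 ± 0.29) were higher, and Btla (-2.09 ± 0.44) and Havcr2 (-1.59 ± 0.31) lower. The list test gave adjusted p = 0.0110, adjusted p = 0.270 with an estimated correlation, and adjusted p = 0.117 without CD103int replicate 2 (0.00111 to 0.361 over all alternatives).

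Other groups also differed. Of 24 cholesterol genes, 4 were higher in CD103int in the paired fit, including Mvd (1.91 ± 0.29) and the squalene synthase gene Fdft1 (1.63 ± 0.30), and 9 in the unpaired fit when adjusted over the list alone. Camera gave an adjusted p of 2.90e-07, and adjusted p = 0.251 with an estimated correlation. Of 16 cytokine genes, 6 were higher and 1 lower in the paired fit, and as many in the unpaired fit when adjusted over the list alone, among them the macrophage growth factor gene Csf1 (4.71 ± 0.58) and the B cell survival factor gene Tnfsf13b (-2.49 ± 0.37). Of 19 chemokine genes, 7 were higher in the paired fit (5 in the unpaired fit when adjusted over the list alone), including Ccl5. Camera gave adjusted p values of 0.00428 and 6.59e-05 for these lists, and adjusted p = 0.270 with an estimated correlation for both. Of 36 interferon response genes, 3 were higher in the paired fit (1 in the unpaired fit when adjusted over the list alone), including Gbp2 (3.04 ± 0.39). That camera call (adjusted p = 0.00208, and adjusted p = 0.604 with an estimated correlation) was lost without CD103int replicate 1 (0.0636; 5.38e-05 to 0.604 over all alternatives). The 26 chemoattractant receptor genes had 5 higher and 4 lower in the paired fit, and as many in the unpaired fit when adjusted over the list alone. Camera did not call that list (adjusted p = 0.439, and adjusted p = 0.604 with an estimated correlation). The higher ones in the paired fit included the receptor gene S1pr1, which guides cells out of tissues and into lymph (4.16 ± 0.58). Of 20 MHC class II presentation genes, 2 were higher and 4 lower in the paired fit (2 and 8 in the unpaired fit when adjusted over the list alone). The lysosomal protease gene Lgmn (2.88 ± 0.30) was higher, and the class II transactivator gene Ciita (-1.94 ± 0.31) lower. The camera call of this list (adjusted p = 0.0408, and adjusted p = 0.604 with an estimated correlation) was lost without CD103hi replicate 1 (0.158) or CD103int replicate 2 (0.404), and without the genes of the sort markers (0.293), with 0.00520 to 0.604 over all alternatives. Of 24 MHC class I and cross-presentation genes, only Nlrc5 was higher in the paired fit (2.10 ± 0.42), and none adjusted over the list alone in the unpaired fit, with a list median of 0.52. The camera call (adjusted p = 0.0411, and adjusted p = 0.604 with an estimated correlation) was lost without CD103hi replicate 2 (0.114) or CD103int replicate 1 (0.837), with 4.00e-04 to 0.837 over all alternatives.

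Markers of other cell types moved with these groups. The alveolar macrophage list had a median of 3.03 in CD103int over CD103hi, with 4 of 23 genes passing in the paired fit and none in the unpaired fit, also when adjusted over the list alone (camera adjusted p = 5.69e-06, and adjusted p = 0.604 with an estimated correlation). Without CD103int replicate 2 it was 1.25 and the camera call was lost (adjusted p = 0.310; 7.00e-17 to 0.865 over all alternatives). Monocyte and interstitial macrophage genes had a median of 2.67 (0.71 with the alveolar macrophage score as a covariate, up to 3.60 over all alternatives), with 5 of 24 higher in the paired fit and 9 in the unpaired fit when adjusted over the list alone (camera adjusted p = 2.80e-10, and adjusted p = 0.413 with an estimated correlation). The cell cycle list had a median of -1.16 with no gene past the threshold in either fit (camera adjusted p = 5.57e-05, and adjusted p = 0.675 with an estimated correlation), and a median of 0.19 without CD103int replicate 1 (adjusted p = 0.468; 8.10e-19 to 0.675 over all alternatives).

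The largest rises in CD103int in the paired fit included the protease gene Adamdec1 (chromosome 14, 68563380 to 68582095, minus strand; 8.76 ± 1.16, adjusted p = 0.0215, with 0 reads in CD103hi replicate 1), the delta opioid receptor gene Oprd1 (6.47 ± 0.82) and the bicarbonate transporter gene Slc4a8 (5.58 ± 0.53). The largest falls included the RNA-binding protein gene Elavl4 (-4.68 ± 0.62), Naalad2 (-4.36 ± 0.56) and the sulfotransferase gene Sult1a1 (-3.63 ± 0.33). The paired fit called 657 genes, 428 higher and 229 lower in CD103int, and the authors' deposited comparison 422 (288 and 134), of which 413 were shared. The unpaired fit called 0 genes in limma and 0 with limma-voom on the recovered reads; without CD103int replicate 2 it called 1285 and without CD103hi replicate 2 it called 1.

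CD103int and CD11b cells were compared to set the intermediate cells against the other cDC lineage. Genes of the cDC1 lineage were higher in CD103int and genes of the cDC2 lineage were higher in CD11b. Xcr1, a sort gene, and Gcsam were higher in CD103int by 5.65 ± 0.30 and 5.90 ± 0.29 (adjusted p = 0.00801 for both), and the cross-presentation receptor gene Clec9a was higher by 4.71 ± 0.41 (adjusted p = 0.0284). Cd163 fell by 6.09 ± 0.66 (adjusted p = 0.0387), and Cd209a fell by 5.80 ± 0.51 (adjusted p = 0.0284), from levels of 10.68 and 10.31 in CD11b to 4.53 and 4.86 in CD103int.

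Of 26 cDC1 genes, 7 were higher in CD103int and none lower (16 adjusted over the list alone; 15 in the paired fit), with a median of 1.95. For these genes camera gave adjusted p = 2.71e-18, and adjusted p = 0.314 with an estimated correlation. Of 26 cDC2 genes, 2 were lower and none higher (14 adjusted over the list alone; 11 in the paired fit), with a median of -2.32, and Clec10a was -5.14 ± 0.47. In camera, adjusted p was 2.49e-12, and adjusted p = 0.314 with an estimated correlation. Of 39 mature migratory DC genes, the lysosomal membrane gene Laptm4b passed in the unpaired fit (6.08 ± 0.69, adjusted p = 0.0428), 18 were higher and 1 lower adjusted over the list alone, and 28 were higher and none lower in the paired fit. The median was 3.06, an 8.31-fold difference, and Bcl2l14 was 6.22 ± 0.56 in the paired fit (adjusted p = 0.00650); camera gave an adjusted p of 1.16e-17, and adjusted p = 0.736 with an estimated correlation. Of 24 MHC class I and cross-presentation genes, none passed in the unpaired fit or adjusted over the list alone, and 4 were higher in CD103int in the paired fit, including the transactivator gene Nlrc5 (2.83 ± 0.42) and Tapbpl (2.54 ± 0.38). The list test gave adjusted p = 5.76e-05, and adjusted p = 0.736 with an estimated correlation. Of 20 MHC class II presentation genes, H2-DMb2 was lower (-2.41 ± 0.30; 3 adjusted over the list alone, 2 in the paired fit), with a list median of -0.58. That camera call (adjusted p = 0.00429, and adjusted p = 0.736 with an estimated correlation) was lost without CD103int replicate 2 (0.182; 5.65e-06 to 0.736 over all alternatives).

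Of 28 NF-kappaB pathway genes, 3 were higher in CD103int in the paired fit, including Traf1 (3.06 ± 0.42), and none in the unpaired fit, also when adjusted over the list alone (camera adjusted p = 2.08e-06, and adjusted p = 0.736 with an estimated correlation). Of 36 regulatory and tolerance-associated genes, none passed in the unpaired fit (4 higher and 2 lower adjusted over the list alone), and in the paired fit 3 were higher, including the inhibitory ligand gene Cd200 (3.13 ± 0.42), and Socs3 was lower (-3.38 ± 0.48). Their median was -0.09, their mean 0.23 and the camera direction down (adjusted p = 0.905). Il12b, which encodes a subunit of the T cell-priming cytokines IL-12 and IL-23, was higher in the paired fit (6.00 ± 0.50, adjusted p = 0.00622). Of 18 co-stimulatory and adhesion ligand genes, Tnfsf8 was lower (-4.93 ± 0.59, adjusted p = 0.0480; 1 higher and 1 lower adjusted over the list alone), and in the paired fit 4 were higher, including the poliovirus receptor gene Pvr (3.81 ± 0.72), and 1 lower. Camera gave an adjusted p of 0.0912 for the list in the unpaired fit and 0.00828 in the paired fit, and adjusted p = 0.688 with the block and an estimated correlation. Without CD103hi replicate 1, CD103hi replicate 2 or CD103int replicate 2 the unpaired value was 0.0270, 0.0225 or 0.00736 (2.19e-04 to 0.859 over all alternatives). Of 24 monocyte and interstitial macrophage genes, 1 was lower in CD103int (5 adjusted over the list alone; 4 in the paired fit), with a median of -1.48 (camera adjusted p = 6.78e-05, and adjusted p = 0.736 with an estimated correlation). The alveolar macrophage list had a median of 0.84 (camera adjusted p = 0.318), with no gene higher in the unpaired fit and 1 in the paired fit, and a median of 2.68 without CD103int replicate 1 (adjusted p = 5.65e-06; up to 0.968 over all alternatives). The cell cycle list had a median of -0.50 and no gene past the threshold in either fit. Its camera call of lower levels (adjusted p = 0.0458, and adjusted p = 0.865 with an estimated correlation) was lost without CD11b replicate 2 (0.799) and with quantile normalization (0.107), with 1.86e-10 to 0.865 over all alternatives. Without CD103int replicate 1 the median was 0.66 (adjusted p = 3.42e-04).

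The largest rises in CD103int in the unpaired fit included Ttc39a (chromosome 4, 109406623 to 109444745, plus strand; 6.54 ± 0.58, adjusted p = 0.0284) and the actin-binding gene Dbn1 (5.15 ± 0.38). Ttc39aos1, annotated on the minus strand beside Ttc39a, was 5.26 ± 0.53, a value that is uncertain if reads were counted without strand. The largest falls included the adrenergic receptor gene Adra2a (-5.08 ± 0.57) and the leukotriene B4 receptor gene Ltb4r1 (-4.16 ± 0.36). In the paired fit the largest rise was that of the protease gene Asprv1 (8.11 ± 0.44, adjusted p = 0.00208), and Retnla (-6.36 ± 0.38) and the IL-33 receptor gene Il1rl1 (-6.18 ± 0.77) were among the largest falls. The unpaired fit called 44 genes, 29 higher and 15 lower in CD103int (50 and 43 with quantile normalization, but 42 and 56 with log2(CPM + 1) and 5 and 8 with limma-voom), the paired fit 486 (322 and 164) and the authors' deposited comparison 352 (227 and 125), and both larger sets held all 44. Without CD11b replicate 1 or 2 limma called 0 genes in the unpaired fit, without CD103hi replicate 1 or 2 it called 4, and without CD103int replicate 1 or 2 it called 18 or 1663.

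Genes higher in 1 subset than in each of the others were counted last. In the unpaired fit 13 genes were higher in CD11b than in both, led by Cd163, Cd209a, Adra2a, Clec10a, Ms4a4c and Tnfsf8, whose smaller log2 fold changes ran from 3.55 to 6.09. No gene was higher in CD103hi or in CD103int than in both others in that fit, or with limma-voom. Both counts need a call in CD103int versus CD103hi, where these fits called 0 genes, so they could only be 0. In the paired fit the counts were 102 for CD11b, 115 for CD103hi and 130 for CD103int. Among those with a mean log2 CPM of at least 4 in the higher subset, the genes with the largest smaller log2 fold changes included Retnla (6.36) and Il1rl1 (6.18) for CD11b, Elavl4 (4.68), Naalad2 (4.36) and Ccdc149 (3.82) for CD103hi, and Oprd1 (6.47), Asprv1 (5.29) and Ccl5 (4.88) for CD103int. Both comparisons of a subset share its libraries. In the paired fit, independent lists of the same sizes would share 7.10, 7.33 and 12.1 genes, and simulated unchanged groups shared 0.03, 0.05 and 0.04 on average over 100 simulations. No gene differed in those simulations, so they do not give the overlap of lists as long as the observed ones. Shared libraries add to such an overlap.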

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

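The alternatives chosen only after the results were seen were limma-voom on the recovered reads with and without the replicate block, the alveolar macrophage score as a covariate, leaving out replicate 2 of both CD103hi and CD103int, the replicate block with CD103int replicate 2 left out, the replicate block together with an estimated correlation in camera, and the lists without the genes of the sort markers. The replicate block itself was planned. Results were genes differing, genes higher in 1 subset, list medians and named genes. A count within 1.5 times of the main one was labelled unchanged. A list or gene was so labelled if it stayed on its side of the threshold, and its direction was checked only where the main test had called it. Uncalled values that changed sign are therefore among the unchanged. Among the comparison counts and the main lists, 317 values under an alternative were unchanged and 67 counts moved by over 1.5 times or to or from 0. Of the list calls, 29 no longer passed, 6 of them in fry, and 4 were gained. Among the other lists and named genes, 6548 values were unchanged by that rule, 1155 passed the threshold newly, 443 no longer passed, 5 were reversed and 1 moved. The filter on low values removed no gene, so leaving it out tests nothing. Quantile normalization moved the median of all genes in CD103int versus CD103hi from -0.01 to -0.12. The cause of the changes below was not tested, and leaving out libraries also lowered their number. The share of genes over 2-fold apart between replicates was 10.7% in CD11b, 12.1% in CD103hi and 35.0% in CD103int. With all 6 libraries in 1 fit, each gene has 1 error variance, which holds the spread of CD103int in every comparison. With only both compared subsets in the fit, the count rose from 339 to 936 for CD11b versus CD103hi. It fell from 44 to 5 for CD103int versus CD11b and stayed at 0 for CD103int versus CD103hi. Where a subset had 1 library left, that library was assumed to vary like the others.

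For CD11b versus CD103hi, the main count of 339 genes became 936 with only both compared subsets in the fit, 861 with the replicate block, 153 with a fold threshold of 2, 804 with limma-voom and the block, 1041 with the covariate, 1381 without both replicates 2, 1258 with the block and without CD103int replicate 2, and 716 in the authors' deposited comparison. For CD103int versus CD103hi, where limma called 0 in the unpaired fit (1836 at an unadjusted p under 0.05), these counts were 657 with the replicate block, 662 with limma-voom and the block, 1333 with the covariate, 1348 without both replicates 2, 1272 with the block and without CD103int replicate 2, and 422 in the authors' comparison. For CD103int versus CD11b, the main count of 44 became 98 with log2(CPM + 1), 93 with quantile normalization, 5 with only both compared subsets, 486 with the replicate block, 5 with the fold threshold, 13 with limma-voom, 577 with limma-voom and the block, 1500 with the covariate, 2439 without both replicates 2, 1525 with the block and without CD103int replicate 2, and 352 in the authors' comparison. Leaving out 1 library at a time gave 2 to 913, 0 to 1285 and 0 to 1663 genes in the 3 comparisons.

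Genes higher in CD11b than in both other subsets, 13 in the main count, numbered 50 with log2(CPM + 1), 28 with quantile normalization, 2 with only the compared subsets, 102 with the replicate block, 0 with the fold threshold in limma, 8 with limma-voom, 146 with limma-voom and the block, 292 with the covariate, 495 without both replicates 2 and 230 with the block and without CD103int replicate 2. With the block, limma-voom and the block, the covariate, both replicates 2 left out, and the block without CD103int replicate 2, CD103hi had 115, 139, 152, 91 and 145 such genes and CD103int 130, 193, 508, 558 and 532. Leaving out 1 library at a time gave 0 to 207 for CD11b, 0 to 121 for CD103hi and 0 to 550 for CD103int.

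With an estimated correlation in camera, which leaves that test 3 residual degrees of freedom, or 2 with the block, no call of the main lists held. For CD11b versus CD103hi the medians and adjusted p were -4.26 and 0.126 for cDC1 genes, 4.83 and 0.126 for cDC2 genes, and 0.83 and 0.263 for regulatory genes. For CD103int versus CD103hi they were -1.55 and 0.270 for cDC1, 2.99 and 0.270 for cDC2, 3.18 and 0.496 for mature, and 0.997 and 0.270 for regulatory genes. For CD103int versus CD11b they were 1.95 and 0.314 for cDC1, -2.32 and 0.314 for cDC2, and 3.06 and 0.736 for mature genes. With the block added, the same medians had adjusted p values of 0.281 for all 3 lists of the first comparison, 0.361, 0.376, 0.376 and 0.361 for the 4 of the second, and 0.688 for all 3 of the third. Fry, which asks whether the genes of a list change on balance and compares them with no other genes, answers another question than camera. A high value in fry does not undo a camera call, but such a list did not pass a test that rests on the spread between libraries. In fry the cDC1 list kept its call in the 3 comparisons (adjusted p = 0.00530, 0.0477 and 0.0263). The cDC2 list kept it in CD11b versus CD103hi (fry adjusted p = 0.0107). For the other called main lists, adjusted p in fry was 0.147 for the regulatory median of 0.83, 0.0952, 0.260 and 0.101 for the medians of 2.99, 3.18 and 0.997, and 0.101 and 0.357 for the medians of -2.32 and 3.06. The mature list in CD11b versus CD103hi, not called in the main test, was called at 1.32 with the covariate and at -1.04 without both replicates 2. The regulatory list in CD103int versus CD103hi was 0.66 (adjusted p = 0.153) with the block and without CD103int replicate 2.

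Leaving out 1 library at a time gave medians from -4.35 to -3.85, -1.93 to -1.20 and 1.76 to 2.57 for cDC1 genes in the 3 comparisons, 3.87 to 6.13, 1.42 to 3.68 and -2.60 to -2.27 for cDC2 genes, -1.04 to 1.18, 2.00 to 4.38 and 1.75 to 4.38 for mature genes, and 0.57 to 0.90, 0.73 to 1.13 and -0.31 to 0.31 for regulatory genes. With the alveolar macrophage covariate, the alveolar macrophage median in CD103int versus CD103hi was -0.028 and the neutrophil median -0.31, both reversed; for the former, the covariate is the list's own mean. Leaving out 1 library gave cell cycle medians from -2.56 to 0.19 in CD103int versus CD103hi and from -1.92 to 0.66 in CD103int versus CD11b. The cell cycle median was reversed to 0.19 in CD103int versus CD103hi without CD103int replicate 1, and in CD103int versus CD11b to 0.01 without CD11b replicate 2 and 0.66 without CD103int replicate 1. Quantile normalization changed the sign of uncalled medians in CD11b versus CD103hi to 0.05 for MHC class II, -0.50 for B cell and -0.37 for T cell genes, and in CD103int versus CD103hi to -0.14 for fibroblast and -0.10 for dissociation stress genes. Without the genes of the sort markers, the MHC class II call in CD103int versus CD103hi was lost (median -0.62, adjusted p = 0.293), as the list then lacks H2-Aa, H2-Ab1 and H2-Eb1. No fold is given for a gene with 3 or fewer reads in both libraries of a compared subset. Where only 1 library was that low (Adamdec1 with 0 reads in CD103hi replicate 1, Asprv1 with 2 and Cd207 with 1 in CD11b replicate 2, Naalad2 with 2 in CD11b replicate 1, Oprd1 with 3 in CD103hi replicate 2, Cd163 with 3 in CD103hi replicate 2), a fold change against that subset depends on the offset of the deposited log2 values.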

Other observations

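Tests chosen only after the result was seen were those of scaling, of dilution and of CD103int as a mixture; the tests of admixed alveolar macrophage RNA and of carry-over into CD103hi replicate 1 were written before.

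Lists of other functions and cell types, less close to the question of the series, gave these values. Microbial pattern recognition genes had 3 of 31 lower in CD11b than in CD103hi (6 higher and 4 lower adjusted over the list alone; 8 and 3 in the paired fit) against a positive median of 0.81 (camera adjusted p = 0.0760 in the unpaired and 0.0227 in the paired fit, and adjusted p = 0.691 with the block and an estimated correlation). That list was called without CD103hi replicate 2 (0.00194), CD103int replicate 1 (0.0322) or CD103int replicate 2 (0.0306), with 8.40e-05 to 0.730 over all alternatives. Endocytic and scavenger receptor genes had 3 of 27 higher and 3 lower (8 and 4 adjusted over the list alone; 8 and 4 in the paired fit), with a median of 2.49 (camera adjusted p = 0.0195, and adjusted p = 0.730 with an estimated correlation); the call was lost without CD11b replicate 1 (0.0814), CD11b replicate 2 (0.0599) or CD103hi replicate 1 (0.101), with 2.29e-08 to 0.730 over all alternatives. Glycolysis genes had a median of 0.32 in this comparison, with Ldhb higher (4.86; 2 genes in the paired fit) and a call (camera adjusted p = 0.0416, and adjusted p = 0.695 with an estimated correlation) that was lost without CD11b replicate 2 (0.0828) or CD103hi replicate 2 (0.108), with 0.0227 to 0.695 over all alternatives. Plasmacytoid DC genes had 2 of 16 higher in CD11b and Ccr9 lower (-4.65; 4 higher and 3 lower in the paired fit), and B cell genes had 2 of 9 higher, Blnk (6.64) and Bank1 (2.83), and Fcrla lower (-4.69; 3 higher and 1 lower in the paired fit). The 4 NK cell genes had a median of 2.88 with Klrd1 higher in CD11b (4.54; 2 genes in the paired fit), of the mast cell and basophil genes Kit was lower (-3.76), and of 8 endothelial genes Pecam1 was higher (3.63) and Esam lower (-4.69). The dissociation stress list had a median of 0.13, with 3 of 28 genes higher in CD11b, including Ier3 (2.53; 4 in the paired fit).

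In CD103int versus CD103hi, T cell genes had a median of 2.92 over 7 genes, with 3 higher in the paired fit, including Tcf7 (3.64), and none in the unpaired fit by limma (1 adjusted over the list alone; camera adjusted p = 0.00353, and adjusted p = 0.270 with an estimated correlation). Without CD103int replicate 2 the T cell call was lost (0.0563; 2.92e-04 to 0.376 over all alternatives). Neutrophil genes had a median of 3.22, with S100a8 higher in the paired fit (3.52; camera adjusted p = 0.0159 in the unpaired fit, and adjusted p = 0.610 with an estimated correlation), and lost the call without CD103hi replicate 1 (0.394) or CD103int replicate 2 (0.883), with 7.65e-06 to 0.883 over all alternatives. Endocytic and scavenger receptor genes (median 1.67, 3 higher and 3 lower in the paired fit) and plasmacytoid DC genes (median 0.76, 5 higher in the paired fit) were not called in the unpaired fit (camera adjusted p = 0.0762 and 0.0863) but were in the paired fit (0.00787 and 0.0342, and adjusted p = 0.585 and 0.376 with the block and an estimated correlation). Without CD103hi replicate 2 or CD103int replicate 1 both were called as well, at 7.21e-05 and 6.37e-04 for the former and 0.0268 and 0.0314 for the latter (up to 0.800 and 0.524 over all alternatives). Fibroblast genes had a median of 0.19 and a mean of -0.17, epithelial genes a median of 0.34 with a camera direction of down, and the 3 erythroid genes a median of 1.53, with 1 higher in the paired fit.

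Alveolar macrophage genes were higher in replicate 2 than in replicate 1 of CD103hi and of CD103int, by medians of 4.31 and 3.78. The median of all genes moved by -0.089 in 1 of these subsets and 0.017 in the other. The values were already normalized, which can hold that median near 0, so this small move by itself does not test scaling or depth. A remaining factor per library would move all genes alike and so would not raise this list alone. Alveolar macrophages carry CD11c, and the gate kept MHC class II-positive, lineage-negative, CD11c-positive cells, so their RNA may have been admixed. The further gates on CD103 and on XCR1 or CCR7 should keep such cells out, and how their RNA would pass these gates was not tested. All 23 genes gained in both subsets, and the log2 ratio of the gains had an SD of 0.224 around a median ratio of 6.93, against 2.02 for all other genes that gained in both and 0.839 for the 42 cell cycle genes, which gained in both as well at a median ratio of 1.89, as admixture in different amounts needs. The SD of 2.02 takes in every other gene with any gain in both, however small. Parts of other lists also had SDs under 0.839, at median ratios of 6.74 (SD 0.403) for 5 of 16 cytokine, 11.1 (0.519) for 6 of 19 chemokine and 3.94 (0.344) for 3 of 7 T cell genes. An even ratio was therefore not particular to the alveolar macrophage list. Further lists gained at similar median ratios with a wider SD, 7.90 (SD 1.05) for all 9 neutrophil genes, 5.46 (1.52) for 9 of 12 lung epithelial, 6.93 (1.72) for 6 of 8 endothelial and 7.11 (2.02) for 6 of 9 B cell genes. A broader admixture of lung cells, beyond alveolar macrophages, therefore stays open. How RNA of these cells would pass the lineage, MHC class II, CD11c and further gates was not tested either. In CD11b, where 22 genes were also higher in replicate 2, no such single ratio was seen, as the gains over those in CD103hi had an SD of 1.85 around a median ratio of 0.596, so that difference is not covered by this test. Examples of the list are Chil3 (4.71 and 10.64 in CD103hi, 9.21 and 13.56 in CD103int) and Lpl (3.72 and 8.26, 7.46 and 11.10). Of the list, 4 genes exceeded a log2 CPM of 4 in CD103hi replicate 1 and 2 are also in another list. No biological explanation was tested, as the design gives none.

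Mature migratory DC genes were lower in replicate 2 than in replicate 1 of CD103hi and of CD103int. Dilution by RNA of cells without cDC1 transcripts would lower the cDC1 list as much. In CD103int the mature list changed by -2.40 and the cDC1 list by -0.40, a difference of -1.999 (95% bootstrap interval -2.27 to -1.48 over 10000 draws). In CD103hi they changed by -1.72 and 0.02, a difference of -1.74 (-2.23 to -1.50). Without the genes of the sort markers these differences were -1.92 and -1.70. The draws resampled genes, which are not independent replicates, so the intervals hold no spread between libraries. These values argue against that dilution only. Added cells with cDC1 but few mature transcripts would lower the mature list alone, and the test cannot exclude them. Carry-over of CD103int-type cells into CD103hi replicate 1 stays open and cannot be told apart from a different state of the cells. Of 39 genes, 38 were higher in that replicate, by a median share of 6.43% of the CD103int replicate 1 level, but the log2 share had an SD of 1.15, between the bounds set for either reading. No biological explanation of this replicate difference was tested.

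The CD103int cells had lower cDC1 and higher cDC2 genes than CD103hi cells, with the mature list highest. As a mixture of CD103hi and CD11b cells, CD103int would need a CD11b share of 77.5% from 25 cDC1 genes and of 16.0% from 23 cDC2 genes. These differ by 61.5 percentage points (95% bootstrap interval 47.5 to 70.6), with 61.8 and 64.3 within replicates 1 and 2. The bootstrap resampled genes, so its interval holds no spread between libraries. Of the 39 mature genes, at least 37 lay above both other subsets within either replicate, which such a mixture forbids. These values cover only a mixture of cells in the state of the CD103hi and CD11b subsets. A mixture of both lineages in a mature state was not tested. Dilution of CD103hi-type cells by cells without cDC1 transcripts cannot be told apart from lower expression, since the log2 fold changes of 18 cDC1 genes had an SD of 0.63, near the 0.426 that replicates give, and ran from -3.58 to -1.22. Without the genes of the sort markers these values were 60.5 percentage points (44.4 to 68.7), at least 36 of 38 mature genes, and an SD of 0.489 over 16 cDC1 genes. That SD is under the bound of 0.5 set for the dilution, which the 0.63 with the sort genes is not. A shared fall in expression would give a small SD as well, so the dilution stays open. Since the sample labels name CCR7 for the sort of CD103int and Ccr7 is in the mature list, the sort alone could select mature cells, and no test here parts this from a difference in lineage.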
